A study of Mus musculus with 30 samples.

How the data were processed

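The series holds 30 mouse mTEC RNA-seq samples, of which 27 are analysed here; 3 samples of B6 x NOD F1 Aire-GFP+ WT cells are not analysed here. Per the labels, mice were female and 4 to 6 weeks old, thymi were digested with collagenase and dispase, CD45+ cells were depleted with magnetic beads, and 1000 cells per library were sorted by flow cytometry into lysis buffer. RNA was captured with anchored oligo(dT), amplified by Smart-seq2 and turned into libraries with Nextera XT, a protocol without unique molecular identifiers or strand. The groups are B6 Aire-GFP+ (3 WT, 2 Aire-KO), NOD Aire-GFP+ (3 WT, 3 Aire-KO) and mTEChi in 8 groups of 2: WT and Aire-KO with PBS or spermidine, WT with DMSO or topotecan, and Foxn1-Cre with Nfe2l2 wt or flox. Doses and treatment times are not given in the sources used here.

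For Aire-GFP+ cells the values are expected counts: the authors deposited kallisto estimated counts per transcript, with TPM and effective lengths beside them. For mTEChi the deposited values are raw counts per gene from featureCounts. The processing notes of the submitters also name STAR, TopHat2 2.1.1 and SAMtools 1.3.1 with build mm10, and give no version for STAR, featureCounts or kallisto. Of 118489 B6 transcripts, 116816 matched GENCODE M21 (GRCm38, mm10) and were summed into 35999 gene symbols and rounded; the 1673 others carry 0.541 to 0.578% of counts. None of the 85723 NOD transcript IDs matched a gene name (0), so NOD was tested per transcript. Of 55011 mTEChi genes, 53009 match GENCODE M21 by symbol.

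Library totals were 6.62 to 12.68 M in B6 Aire-GFP+, 4.21 to 5.34 M in NOD and 2.03 to 5.72 M in mTEChi, and the 20 most abundant features took 11.91 to 17.58, 9.45 to 12.92 and 11.89 to 14.59% of counts. B6 libraries, in order WT 1 to 3 and KO 1 and 2, had 6.62, 10.13, 9.54, 9.88 and 12.68 M. NOD libraries, WT 1 to 3 and KO 1 to 3, had 4.36, 4.21, 5.27, 5.34, 5.25 and 4.59 M. The mTEChi libraries, replicates 1 and 2, had 2.66 and 2.03 (WT PBS), 2.75 and 2.23 (WT spermidine), 2.58 and 3.18 (KO PBS), 2.27 and 2.10 (KO spermidine), 3.33 and 3.36 (DMSO), 2.89 and 2.95 (topotecan), 4.78 and 4.40 (Nfe2l2 wt) and 4.29 and 5.72 (flox) M. Replicates of a group differed by more than counting error, with chi-square per degree of freedom between 3.05 and 19.7 for features of 20 counts or more in a pair, so p values rest on the spread between libraries. The biological coefficient of variation was 0.272 in B6, 0.517 in NOD and 0.269 in mTEChi.

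Counts were tested with edgeR 4.0.16 (quasi-likelihood fit, TMM scaling, filterByExpr) in R 4.3.3, with Benjamini-Hochberg adjustment and calls at adjusted p < 0.05. All 16 mTEChi libraries shared one fit with a group mean each, and B6 and NOD were fitted apart. The comparisons were Aire-KO against WT in B6, NOD and PBS mTEChi, spermidine against PBS in WT and in Aire-KO cells and the difference of these effects, topotecan against DMSO, and Nfe2l2 flox against wt. The Aire-induced set is the genes called lower and at least 2-fold down in B6 Aire-KO cells, and the Aire-repressed set the genes called higher and at least 2-fold up. Sets and 32 fixed lists of pathway and cell-type genes, each with 4 or more tested members, were tested with camera in limma 3.58.1 at a preset correlation of 0.01, again with the correlation estimated, and with fry. Camera p values of the Aire-induced set were adjusted over the 6 mTEChi comparisons and those of the lists over the lists of a comparison, and members also over the list alone. Set medians were placed among 10000 random lists matched on expression in 20 bins. Shares of counts and detected genes were compared at equal depth by exact permutation, where 2 against 2 libraries cannot go below p = 0.333 and 3 against 2 or 3 against 3 not below 0.1.

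Named genes follow a rule written before the data were examined: the targeted gene, Aire and Top1, then up to 10 largest changes per direction among genes with adjusted p < 0.05, a mean of 5 CPM or more and no overlap between groups, and the 5 smallest p values per direction where fewer pass. Predicted, clone, pseudogene and receptor-segment names were left out. Some genes that meet the rule are not reported here. A group without counts was given a floor of 3 counts over the group, and such folds are written "at least". Groups, comparisons, tests, lists and the alternatives in the closing section were chosen before the data were examined, apart from those stated there. The alternatives were other scaling, filters and tools (DESeq2 1.42.0, limma-voom, edgeR glmTreat at a fold of 1.5), an offset for effective length, other definitions of the set, the replicate number as a block, fits to single experiments and leaving out each library. Leaving out a library also changes the filter, scaling and dispersion. For example, 20567 mTEChi genes were tested without KO PBS replicate 1, against 18418 with all libraries.

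The steps were tested on simulated data made from the real libraries, drawn once, with 200 changed genes per comparison, 50 at each fold. The Aire-KO comparisons had far more calls in the real data (7410 in B6, 2018 in NOD, 1896 in PBS mTEChi). More changed genes ease the adjusted threshold, so the shares below need not hold there. At a fold of 2 the share found was 30% in B6, 2% in NOD, 14% in PBS Aire-KO, 8% and 14% for spermidine in WT and Aire-KO cells, 4% for their difference, 16% for topotecan and 22% for Nfe2l2. At a fold of 4 it was 70, 18, 48, 60, 42, 34, 52 and 50%. A list of 2000 genes shifted by -0.2 in log2 was found in each comparison with gene names (camera p of 0.00506 or less), and an unchanged list was not (0.496 or more). Fry, which tests a list alone, did call the unchanged list in B6, PBS Aire-KO and topotecan. The fitted medians of that list were 0.0128, 0.0315 and 0.0315. Its median was positive in every comparison with gene names (0.00965 to 0.0315). Scaling gives that direction when the other list is lowered, so the unchanged list moved slightly. Whether fry is lenient as well cannot be told. Simulated genes were drawn independently and in lists of 2000, so these checks do not cover short lists of correlated genes. Tables and plots used Python 3.11.15 with pandas 2.3.3, numpy 2.4.6 and matplotlib 3.10.9.

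Several planned steps could not be run because NOD transcripts carry no gene names: the Aire-KO effect in NOD against B6, NOD against B6 WT cells, the set test in NOD and a fit of both strains. No genome sequence was used here, so promoter sequence and Z-DNA motifs were not analysed here.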

Results

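Medullary thymic epithelial cells (mTECs) use the transcription regulator Aire to express genes of peripheral tissues, and the 27 libraries analysed here ask which transcripts follow Aire, spermidine, topotecan and Nfe2l2. Each library came from 1000 sorted mTECs of female mice aged 4 to 6 weeks. Aire-GFP+ cells were profiled on the B6 background (3 WT, 2 Aire-KO, 6.62 to 12.68 M counts) and the NOD background (3 WT, 3 Aire-KO, 4.21 to 5.34 M). The 16 mTEChi libraries form 8 groups of 2 (2.03 to 5.72 M counts): WT and Aire-KO with PBS or spermidine, WT with DMSO or topotecan, and Foxn1-Cre mice with Nfe2l2 wt or flox. Levels are CPM after TMM scaling, given as mean ± SD, and adjusted p values are from edgeR unless another test is named. These p values measure spread between libraries, which nothing in the labels ties to separate animals. Intervals and lower bounds cover counting error only. Fits with a library left out also change the filter, scaling and dispersion, so a call lost there need not rest on that library.

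Aire itself was still read in the knockouts. B6 Aire-GFP+ Aire-KO cells carried 1641 ± 188 CPM (n = 2) on Aire against 1653 ± 44.1 in WT (n = 3), log2 fold change -0.01 (SE 0.0952, adjusted p = 0.938). In PBS mTEChi, Aire rose 2.83-fold in Aire-KO cells, from 1630 ± 12.5 to 4616 ± 650 CPM (log2 1.5, SE 0.138, adjusted p = 3.41e-05, n = 2 each; KO libraries 5075 and 4156, WT libraries 1621 and 1638). The gene lies on chromosome 10 at 78030022 to 78043610. Gene-level counts therefore do not check the knockout, and the structure of the targeted allele is not given in the sources used here.

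**Figure D1:**
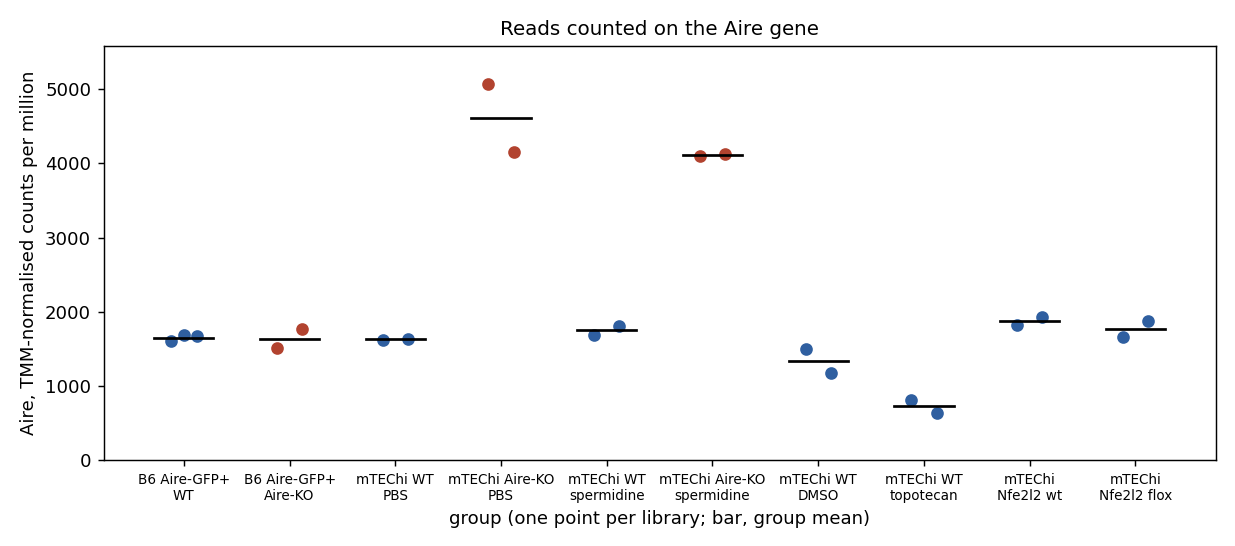
Aire level in CPM (vertical axis) for each B6 Aire-GFP+ and mTEChi library (points) in 10 groups, with bars at group means and Aire-KO groups in red. The Aire-KO mTEChi groups sit highest, at means of 4616 (PBS) and 4111 (spermidine), and the topotecan group lowest at 730.

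What does loss of Aire remove from B6 Aire-GFP+ cells? Reg3b, an antimicrobial lectin of the gut, fell from 145 ± 110 CPM in WT to no counts in Aire-KO cells (adjusted p = 7.23e-04, n = 2 and 3). That is at least 915-fold lower. Its fitted log2 of -13.8 to -12.6 over single leave-outs is set against no counts, so only the bound gives a size. The gut peptide genes Nts and Pyy went the same way, from 107 ± 38.1 and 62.1 ± 11.3 CPM to no counts, at least 675-fold and 393-fold lower. Other genes without a count in the knockout were Prss29, a protease (at least 647-fold), Lefty2, a signalling ligand of the embryo (548-fold), Cytl1 (382-fold), the liver cytochrome Cyp1a2 (337-fold), Gpr50 (313-fold), the carbonic anhydrase Car4 (306-fold) and the milk casein Csn1s2a (300-fold). In the other direction Ctla4, an inhibitory receptor best known from T cells, rose 14.7-fold (10.2 ± 5.65 to 153 ± 5.97 CPM, log2 3.87, SE 0.39, adjusted p = 2.55e-04; chromosome 1, 60887000 to 60915832). The retinal receptor Rgr rose 11.8-fold (4.63 to 55.2 CPM), Acot12 9.95-fold, Htra4 9.28-fold and Fam19a1 9.04-fold. The olfactory receptor Olfr1136 rose 8.52-fold, the synaptic gene Syn2 8.25-fold, Sox21 7.14-fold and the acetylcholine receptor subunit Chrna5 7.10-fold.

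In all, 7410 of 17923 tested genes changed, 3410 higher and 4000 lower. Leaving out KO replicate 2 gave 4785 calls (2262 higher, 2523 lower), KO replicate 1 gave 5259, and leaving out a WT library gave 5951 to 6961. Among changes of at least 2-fold the balance tilts to losses, with 1343 genes higher and 3152 lower in Aire-KO cells; 542 of those 3152 (17.2%) had no count there. These 3152 genes are called the Aire-induced set below, and the 1343 the Aire-repressed set. The induced set took 6.82 ± 0.240% of all counts in WT and 1.36 ± 0.0469% in Aire-KO cells, a fall fixed by the selection because the same libraries defined the set. Genes detected at equal depth went from 22728 ± 266 to 19912 ± 258 (exact p = 0.1, the smallest value that 3 against 2 libraries allow). The split between rises and falls depends on scaling and tool. With library totals alone, 1591 genes rose and 6250 fell, as the median log2 fold change moved from -0.12 to -0.51, and limma-voom called 3497 higher and 3343 lower.

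**Figure D2:**
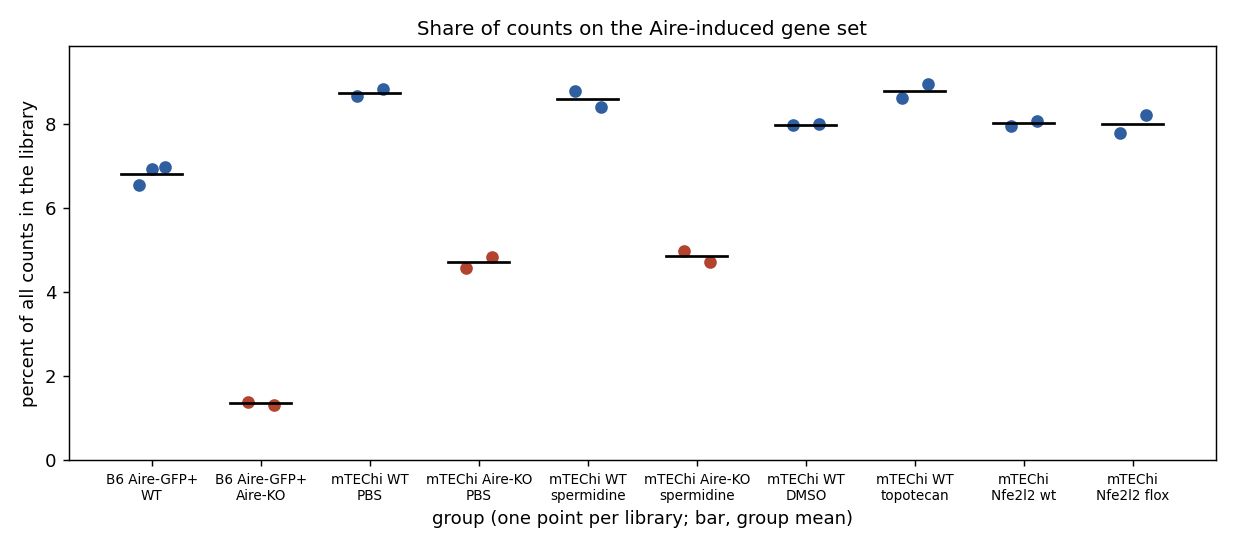
Percent of all counts on the Aire-induced set (vertical axis, from 0) in each B6 Aire-GFP+ and mTEChi library (points), with bars at group means and Aire-KO groups in red. The B6 groups come from the libraries that defined the set; in PBS mTEChi the mean is 8.75 in WT and 4.71 in Aire-KO cells, and in topotecan 8.80 against 7.99 in DMSO.

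Tissue genes long used as markers of Aire function fell in the comparison Aire KO vs WT, B6 Aire-GFP+: of 24 tested, 21 were lower and 2 higher (median log2 -6.55, camera adjusted p = 7.51e-24; adjusted p = 0.107 with an estimated correlation). The fibrinogen gene Fgg fell from 69.6 to 0.0595 CPM and Pcp4 11.5-fold. MHC class II genes, which present antigen to CD4 T cells, went up: 9 of 12 rose and 2 fell (median 1.11, camera adjusted p = 4.60e-08; 0.184 with an estimated correlation), among them H2-Ab1 2.40-fold to 44586 CPM, Ctss 3.56-fold and H2-Aa 2.22-fold. In the MHC class I list 8 of 13 rose and 2 fell (median 0.52, adjusted p = 0.0251; 0.310 with an estimated correlation), with B2m 1.85-fold and Psmb8 1.83-fold higher; this call is lost with library totals alone (adjusted p = 0.224) and without WT replicate 3 (0.0571). Interferon response genes fell, 14 of 22 lower and 2 higher (median -0.78, adjusted p = 0.00517; 0.310 with an estimated correlation), with Isg15 15.8-fold lower. Among lists for mTECs that mimic peripheral cell types, secretory (median -3.15, 0 higher and 5 lower of 8), enterohepatocyte (-1.48, 1 and 6 of 10) and ionocyte (-0.99, 0 and 4 of 7) genes fell, at adjusted p = 0.00141, 0.00517 and 0.0323, and at 0.310, 0.310 and 0.586 with an estimated correlation; the ionocyte call is lost without WT replicate 3 (0.0571). Muscle genes fell as well (median -1.41, 0 higher and 4 lower of 10; adjusted p = 0.0323, 0.320 with an estimated correlation), a call lost without WT replicate 3 (0.0571) or KO replicate 2 (0.0712). The tuft, microfold, ciliated, keratinocyte and neuroendocrine lists did not pass. Cell cycle genes were lower (median -0.72, 1 higher and 14 lower of 31; adjusted p = 0.0323, 0.788 with an estimated correlation), but not without WT replicate 1 (0.0902) or 3 (0.0676) or KO replicate 2 (0.115). Lipf and Foxi1, markers of gastric and ionocyte identity, were 0 and 0.178 CPM in KO against 12.2 and 15.4 in WT. Fibroblast genes did not pass as a list (median -1.27, 2 higher and 4 lower of 9, adjusted p = 0.1425; Col1a1 at 0.331 against 32.0 CPM), and neither did thymocyte genes (median -0.02, adjusted p = 0.926).

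Does the same follow in NOD mice? The NOD table lists transcripts under strain-specific IDs that no reference used here links to gene names, so the test is per transcript and gives no gene names. Of 27690 transcripts 2018 changed, 924 higher and 1094 lower, and among those of at least 2-fold 523 rose and 958 fell. The transcript T0062825.1 (prefix MGP_NODShiLtJ_) fell from 67.3 ± 10.9 CPM to no counts, at least 319-fold (adjusted p = 0.00274, n = 3 each), and T0092767.1 rose from no counts to 22.2 ± 2.67 CPM, at least 105-fold (adjusted p = 0.00542). Detected transcripts at equal depth went from 47829 ± 125 in WT to 43825 ± 635 in Aire-KO (exact p = 0.1, the smallest possible with 3 against 3). The number of calls moves with the libraries: leaving out any WT library or KO replicate 2 or 3 gave 472 to 822 calls, and leaving out KO replicate 1 gave 1498. Library totals alone gave 687 higher and 1389 lower, and limma-voom the opposite balance, 744 higher and 282 lower. With the replicate number as a block only 93 calls were left, 57 higher and 36 lower.

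Do mTEChi, which were sorted without the GFP reporter, lose the same genes? In PBS mTEChi Aire-KO cells, Nts fell again from 46.8 ± 27.0 CPM to no counts (at least 81.1-fold, adjusted p = 0.00270, n = 2 each), as did Prss29 (at least 73.0-fold). Sbpl, Retnla, a resistin-like cytokine, and the relaxin Rln3 were also without counts, at least 68.2-fold, 66.8-fold and 56.2-fold lower. Over single leave-outs the fitted log2 of Nts ran from -10.8 to -9.48 and that of Rln3 (32.4 ± 22.7 CPM in WT) from -10.3 to -8.75. These values are set against no counts, so only the bounds give sizes. The falls of Oas1e, Prss34, Calb2, Rhcg and Crisp3 to no counts (at least 124-fold, 114-fold, 55.4-fold, 43.6-fold and 42.2-fold) passed with all libraries but each lost the call when either KO library was left out, and all but Crisp3 also without WT replicate 1 (highest adjusted p = 0.0825, 0.139, 0.0678, 0.0897 and 0.0594). Their bounds rest on uneven WT pairs: Oas1e read 71.2 ± 79.5 CPM, Calb2 32.0 ± 31.5, Prss34 65.9 ± 23.2, Rhcg 25.2 ± 16.4 and Crisp3 24.3 ± 14.5. Over single leave-outs the fitted log2 of Oas1e ran from -11.7 to -8.60 and that of Calb2 from -10.5 to -7.97, again against no counts and so not sizes. Olfr1136 rose 15.5-fold (1.94 to 30.1 CPM, log2 3.96, SE 0.700, adjusted p = 0.00253), Acot12 11.3-fold, Rgr 10.2-fold, St6galnac3 7.99-fold and the muscle gene Myot 7.36-fold. The sizes are loose, above all for Acot12 (3.70 ± 3.69 CPM in WT) and Rgr (4.12 ± 3.77), although each of these genes kept its call in every leave-out. Over these the log2 ran from 3.61 to 4.33 for Olfr1136, 2.66 to 5.14 for Acot12, 2.58 to 4.76 for Rgr, 2.72 to 3.39 for St6galnac3 and 2.55 to 3.24 for Myot. Cbln4 (14.7-fold), Siglec15 (13.7-fold), Neu2 (8.13-fold) and Gabra4 (6.99-fold) passed as well, but Cbln4 and Siglec15 kept the call only without KO replicate 2, and Neu2 and Gabra4 in no leave-out (highest adjusted p 0.0883, 0.182, 0.168 and 0.265 over single leave-outs). Their log2 ran from 3.50 to 4.18, 2.91 to 5.04, 2.53 to 3.66 and 2.14 to 3.82 over these.

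In total 1896 of 18418 genes changed in PBS mTEChi, 960 higher and 936 lower, and of those at least 2-fold 466 rose and 801 fell. Of the genes tested in B6 and mTEChi, 612 fell in both (204 expected by chance) and 628 rose in both (182 expected), while 39 and 17 went opposite ways (199 and 185 expected; Fisher exact adjusted p = 1.91e-198 and 6.12e-247 for the shared falls and rises, with genes counted as independent). The Aire-induced set defined in B6 cells fell as a whole: median log2 -1.46 over 2712 genes, 557 lower and 6 higher, or 859 and 14 when adjusted over the list alone (camera adjusted p = 2.43e-28, 6.14e-07 with an estimated correlation), where matched random lists span -0.18 to -0.12. The Aire-repressed set rose, median 0.57, with 352 of 1239 higher and 4 lower. The induced set took 8.75 ± 0.123% of counts in WT and 4.71 ± 0.173% in Aire-KO cells (exact p = 0.333, the smallest value with 2 against 2). Leaving out WT replicate 1 or 2 gave 1075 or 1185 calls, and KO replicate 1 or 2 gave 636 or 903. With library totals alone 581 genes rose and 1387 fell, while limma-voom called 763 higher and 305 lower, so the balance of rises and falls depends on both scaling and tool.

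MHC class II genes rose in mTEChi as well, 11 of 12 higher and 1 lower (median 0.89, camera adjusted p = 9.36e-21, 0.00174 with an estimated correlation): H2-Ab1 2.00-fold to 26166 CPM and H2-Aa 1.88-fold. The classic Aire targets fell, 15 of 22 lower and 1 higher (median -5.40, adjusted p = 1.88e-16, 0.00174 with an estimated correlation), with the trefoil factor Tff3 from 21.7 CPM to 0. Interferon genes fell, 11 of 22 lower and 1 higher (median -0.75, adjusted p = 5.88e-07, 0.0472 with an estimated correlation), with Isg15 3.14-fold and Oasl2 1.84-fold lower. Of the 9 mimetic cell lists, 6 fell: tuft, microfold, enterohepatocyte, ionocyte, secretory and ciliated genes (camera adjusted p = 4.51e-07, 8.01e-05, 0.00130, 0.00364, 0.00766 and 0.0298). With an estimated correlation the enterohepatocyte list kept its call (adjusted p = 0.0472), and the tuft, microfold, secretory (each 0.148), ionocyte (0.0553) and ciliated (0.518) lists did not. Tuft genes went to a median of -1.45 (7 of 12 lower, 10 over the list alone; Alox5ap 3.03-fold, Avil 2.76-fold), and microfold genes to -0.78 (4 of 10, 5 over the list alone; Gp2 10.3-fold, Ccl20 7.05-fold). Enterohepatocyte genes went to -2.29 (5 of 10 lower and 2 higher; Saa1 31.7-fold), ionocyte genes to -1.97 (3 of 7, 5 over the list alone), secretory genes to -3.25 (2 of 9) and ciliated genes to -1.97 (2 of 10, 5 over the list alone). The ciliated call was also lost without WT replicate 2 (0.0721). Muscle (median 0.64, adjusted p = 0.710), neuroendocrine (median -0.09, camera direction up, 0.620) and keratinocyte (-0.94, 0.206) lists did not pass. Fibroblast genes were lower in Aire-KO cells (median -2.50, 4 of 10 lower; adjusted p = 0.00393, 0.391 with an estimated correlation; Col1a1 1.26 against 84.9 CPM). Thymocyte (median -0.64), endothelial (-0.42) and erythroid (-2.20) lists did not pass.

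Spermidine is a polyamine that favours Z-DNA in vitro, so does it shift Aire-induced genes in WT mTEChi? No gene passed in WT cells (0 of 18418, edgeR; 709 genes at unadjusted p < 0.05 where 921 are expected by chance; 0 calls with DESeq2 and 0 with limma-voom). Without a low-count filter 111 genes were called, 56 higher and 55 lower. Among the smallest p values, none passed: the cytokine Il23a read 92.9 ± 4.33 CPM against 165 ± 28.3 (log2 -0.83), Nefm -2.89, the collagen Col6a4 -1.10, P3h2 1.18, Fmo1 1.49, Igsf1 2.46, Rbm18 0.75 and Lmbr1l 0.93, all at adjusted p = 0.999. Aire was 1752 ± 86.4 against 1630 ± 12.5 CPM (log2 0.10, SE 0.135). The Aire-induced set had a median log2 of 0.03 (0 higher and 0 lower; camera adjusted p = 0.855), above the matched random span of -0.01 to 0.02 but without a call by the test. Its share of counts was 8.60 ± 0.268% against 8.75 ± 0.123% (exact p = 0.667). Hemoglobin genes were lower by list, median -3.05 over 7 erythroid genes (camera adjusted p = 6.50e-05, 0.547 with an estimated correlation; 0 lower, 4 over the list alone), as Hbb-bs read 3.60 against 115 CPM and Hba-a1 1.5 against 46.1. Hemoglobin genes are markers of red cells, and the source of these reads was not tested. Without spermidine replicate 2 the erythroid call is lost (adjusted p = 0.0918). Cell cycle genes (median -0.33, adjusted p = 0.00298, 0.710 with an estimated correlation) and tuft genes (median 0.34, 0.00370 and 0.710) had no member that passed, and both calls are lost without PBS replicate 2 (0.226 and 0.748) and without spermidine replicate 1 (0.206 and 0.0606). On simulated data the test found 8% of 2-fold and 60% of 4-fold changes in this comparison, so small effects of spermidine are open.

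In the comparison Spermidine vs PBS, Aire-KO mTEChi, 1 gene passed. The centrosome gene Cep85 fell 3.70-fold, from 1181 ± 108 CPM with PBS to 319 ± 35.6 (log2 -1.89, SE 0.232, adjusted p = 0.0178, n = 2 each; chromosome 4, 134129858 to 134187112). The call is lost whichever library is left out (adjusted p 0.0916 to 0.315). Without a low-count filter 76 genes were called, 41 higher and 35 lower. Its neighbours Ubxn11 (log2 -1.13) and Sh3bgrl3 (-0.54), which overlap each other, did not pass (both adjusted p = 0.833), nor did Apoa1 (-3.12) or the chemokine Cxcl12 (22.6 to 59.8 CPM, log2 1.41, adjusted p = 0.706). The Aire-induced set had a median of 0 (0 higher and 0 lower; camera adjusted p = 0.855). Thymocyte genes were higher, median 1.16 over 14 genes (camera adjusted p = 1.34e-07, 0.0386 with an estimated correlation; 0 passed over all genes, 3 over the list alone), with Cd3e at 12.9 against 2.86 CPM. Endothelial genes were higher too (median 1.36; adjusted p = 1.31e-04, 0.359 with an estimated correlation; Cdh5 4.95 against 0.779 CPM), a call lost without PBS replicate 1 (0.0622). Cell cycle genes were lower (median -0.49, adjusted p = 7.80e-09) and tuft genes higher (0.49, 1.31e-04), each without a passing member and each at 0.359 with an estimated correlation. Interferon (median 0.22, adjusted p = 0.00145), immediate early (0.21, 0.0101) and keratinocyte (-0.33, 0.0148) lists passed as well, without a passing member and at 0.359, 0.603 and 0.603 with an estimated correlation. All of these calls are lost without PBS replicate 1 (0.185, 0.0622 and 0.601), and the immediate early and keratinocyte calls also without spermidine replicate 2 (0.0720 and 0.569).

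Does the spermidine effect differ between WT and Aire-KO cells? In the comparison Spermidine effect, WT minus Aire-KO mTEChi, no gene passed (0 of 18418, edgeR; 619 at unadjusted p < 0.05 with 921 expected; 1 with limma-voom, 3 with DESeq2 and 78 without a low-count filter). Cep85 came closest, with a difference in log2 of 2.34 (SE 0.322, adjusted p = 0.0684, n = 2 in each of 4 groups). Apoa1 (4.12, adjusted p = 0.701), Cpxm1 (-1.76, 0.407) and Cxcl12 (-1.78) did not pass. The Aire-induced set had a median difference of 0.01, with the camera direction down (adjusted p = 0.855). Erythroid (median -3.02), thymocyte (-0.81) and interferon (-0.25) lists differed at camera adjusted p = 0.00559, 0.0191 and 0.0133, all without a passing member and all at 0.391 with an estimated correlation; each is lost without WT spermidine replicate 2 (0.112, 0.274 and 0.182). The erythroid call is also lost without Aire-KO spermidine replicate 1 (0.6245), the thymocyte call without WT PBS replicate 1 (0.189) or Aire-KO spermidine replicate 2 (0.0513), and the interferon call without WT PBS replicate 2 (0.174) or Aire-KO PBS replicate 1 (0.182).

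**Figure D3:**
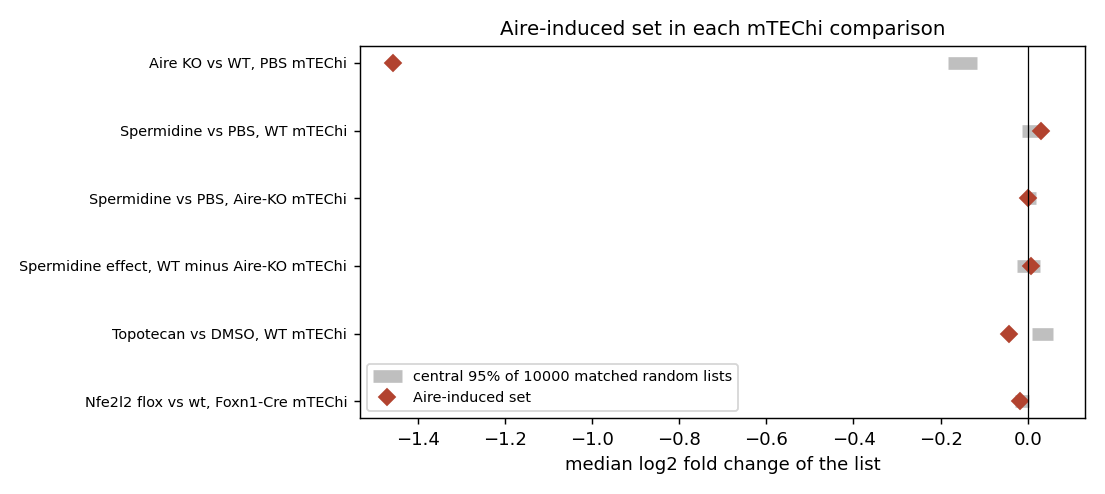
Median log2 fold change of the Aire-induced set (diamonds, horizontal axis) in each mTEChi comparison, with grey spans for the central 95% of 10000 random gene lists matched on expression. PBS Aire-KO lies at -1.46 and topotecan at -0.04, below their spans; spermidine in WT lies at 0.03, just above its span.

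Topotecan traps topoisomerase 1 on DNA, and the question is whether Aire-induced genes follow. Its target gene Top1 did not pass (110 ± 12.6 against 90.1 ± 6.83 CPM in DMSO, log2 0.28, SE 0.164, adjusted p = 0.473, n = 2 each). Aire fell 1.84-fold, from 1340 ± 227 to 730 ± 126 CPM (log2 -0.88, SE 0.136, adjusted p = 0.0125; 1500 and 1180 against 819 and 640 per library), but this call is lost without DMSO replicate 1 (adjusted p = 0.0784) and when the 4 libraries are fitted alone (Aire log2 fold change, Topotecan vs DMSO, WT mTEChi, -0.88, adjusted p = 0.288). Meltf, a melanotransferrin, fell 16.2-fold (42.6 ± 1.93 to 2.60 ± 0.0721 CPM, log2 -4.02, SE 0.518, adjusted p = 0.00632) in every leave-out. The stomach and pancreas enzymes Pgc (34.2 to 0.478 CPM) and Cel (11.2 to 0.159) and the zinc finger gene Zcchc12 (25.8 to 0.159) fell as well and kept the call in every leave-out, on few counts. Over the leave-outs their log2 ran from -9.77 to -5.11, -8.16 to -4.98 and -9.37 to -5.60. The low ends, without topotecan replicate 2, are fitted against a topotecan library without counts and are not sizes. Chgb, a granin of endocrine cells (at least 61.4-fold lower), Gabrr1 (at least 39.6-fold), Ccn5 (at least 31.8-fold), Ctrb1 (16.7-fold), Mfap4 (18.8 to 0.637 CPM) and Reg3a (10.6 to 0.490) passed too, but each lost the call without topotecan replicate 1 or 2, Chgb, Ctrb1 and Mfap4 also without DMSO replicate 1 and Ccn5 also without DMSO replicate 2 (highest adjusted p 0.154, 0.0517, 0.0817, 0.128, 0.0912 and 0.0573 over single leave-outs). Their sizes are loose too. The DMSO pairs are uneven for Chgb (29.9 ± 36.0 CPM), Gabrr1 (19.3 ± 19.1) and Ccn5 (15.5 ± 14.2). Over single leave-outs the fitted log2 ran from -10.5 to -6.84 for Chgb, -9.70 to -7.21 for Gabrr1, -9.34 to -7.14 for Ccn5, -9.16 to -3.06 for Ctrb1, -8.91 to -3.84 for Mfap4 and -4.90 to -3.93 for Reg3a. Chgb, Gabrr1 and Ccn5 had no counts with topotecan, so only their bounds give sizes. The same holds for a low end fitted to a lone topotecan library without counts, as for Mfap4. Upward, Clec4f, a lectin known from liver macrophages, rose 18.4-fold (3.0 ± 2.25 to 55.8 ± 28.4 CPM, log2 4.21, SE 0.626, adjusted p = 0.0124) and kept the call in every leave-out. The log2 was 3.55 without DMSO replicate 2 and 5.27 without DMSO replicate 1. Bco1 (17.4-fold), Cela2a (16.5-fold), Gkn1 (8.73-fold), Fetub (8.01-fold), Fbp2 (6.34-fold), Car7 (5.71-fold), Slc11a1 (5.56-fold), Xkrx (5.55-fold) and Lefty2 (5.08-fold) rose in the full comparison but each lost the call without DMSO replicate 1 (adjusted p 0.0684 for Bco1 to 0.205 for Fbp2) and in at least 1 other leave-out, Xkrx in all 4 (0.0522 to 0.185). Their sizes are as loose, with a log2 of 2.73 to 4.72 for Cela2a and 1.79 to 3.76 for Slc11a1 over single leave-outs.

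Over all genes 120 changed with topotecan, 36 higher and 84 lower, and 2566 had an unadjusted p < 0.05 where 921 are expected. The balance depends on the tool, with 30 higher and 30 lower by limma-voom and 131 higher and 280 lower by DESeq2. The count moves widely: 45 without DMSO replicate 1, 60 with limma-voom, 411 with DESeq2 and 1006 without a filter. When these 4 libraries are fitted alone, which changes the filter, scaling and dispersion together, 1 gene is called and 0 of the 120, so each gene named above loses its call there. The 120 calls use a spread shared over all 16 mTEChi libraries. Chi-square per degree of freedom was 8.22 in the DMSO pair and 10.7 in the topotecan pair. It was 3.05 to 6.08 in PBS and spermidine pairs, and 8.47 and 8.54 in Nfe2l2 pairs. Depth differs as well, and whether the shared spread is too small for topotecan was not tested. Of 80 genes lower with topotecan that were also tested in B6 cells, 29 belong to the Aire-induced set (13.9 expected, Fisher exact adjusted p = 5.18e-05), as do 11 of 36 higher genes (6.24 expected, 0.0457). The overlap is not particular to induced genes, since 15 of the 80 belong to the Aire-repressed set (6.33 expected, Fisher exact adjusted p = 0.00274), and 5 of the 36 (2.85 expected, 0.203), a test chosen after results were seen. The set as a whole leaned only slightly down: median log2 -0.04, mean -0.18, 29 lower and 11 higher (62 and 25 over the list alone), below all 10000 matched random lists (0.01 to 0.06) but without a call (camera adjusted p = 0.808, 0.434 with an estimated correlation). The median turns with the set taken from PBS mTEChi instead (0.15) and without DMSO replicate 1 (0.05). In the PBS mTEChi set the mean stayed negative (-0.10), with 20 genes lower and 11 higher. The share of counts on the Aire-induced set was higher with topotecan, 8.80 ± 0.236% against 7.99 ± 0.00561% (exact p = 0.333, the smallest possible). Fewer genes of that set were detected at equal depth, 2648 ± 19.1 against 2708 ± 43.1 (exact p = 0.333). All detected genes went the other way, 29564 ± 220 against 28353 ± 868. Long genes were not hit harder: across 18141 genes the Spearman correlation of the log2 fold change with genomic span was 0.0328, and median changes from the shortest to the longest class of 5 were 0, -0.02, -0.02, 0.02 and 0.06. Genes are not independent replicates in such a correlation.

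Of the pathways in the comparison Topotecan vs DMSO, WT mTEChi, MHC class II genes fell, 2 of 12 lower and 9 over the list alone (median -0.33, camera adjusted p = 1.53e-05, 0.243 with an estimated correlation): H2-Ab1 1.27-fold from 10157 CPM (adjusted p = 0.0202) and H2-DMb2 1.5-fold (0.0236). Cell cycle genes were lower (median -0.52 over 31, adjusted p = 1.22e-05, 0.575 with an estimated correlation) without a passing member, as Rrm2 read 36.5 against 99.8 CPM; without DMSO replicate 2 that call is lost (0.193). Tuft genes were higher (median 0.70, adjusted p = 8.15e-05, 0.575 with an estimated correlation; 0 of 12 passed, 2 over the list alone), with Alox5ap at 110 against 54.8 CPM. Microfold genes had a median of 0.38 (adjusted p = 0.0280, 0.575 with an estimated correlation), with Marcksl1 1.80-fold higher (adjusted p = 0.0265) and Gp2 at 573 against 120 CPM, and lost the call without DMSO replicate 2 (0.508). The p53 targets, a readout of DNA damage, did not pass as a list (median -0.13, 1 higher and 0 lower of 26, adjusted p = 0.401), although Plk2 rose 2.01-fold (adjusted p = 0.0440). Calls without a passing member, at 0.575 with an estimated correlation, were MHC class I (median -0.12), muscle (-2.01), ciliated (1.58) and immediate early (0.22) genes (each adjusted p = 0.0280) and keratinocyte genes (0.47, 0.0103). The class I, muscle, ciliated and immediate early calls are lost without DMSO replicate 1 (0.148, 0.648, 0.327 and 0.349), the ciliated, immediate early and keratinocyte calls without topotecan replicate 2 (0.721, 0.217 and 0.102), and the class I call without topotecan replicate 1 (0.109). Thymocyte (median 0.50), endothelial (0.50), fibroblast (0.57) and erythroid (0.38) genes did not pass.

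**Figure D4:**
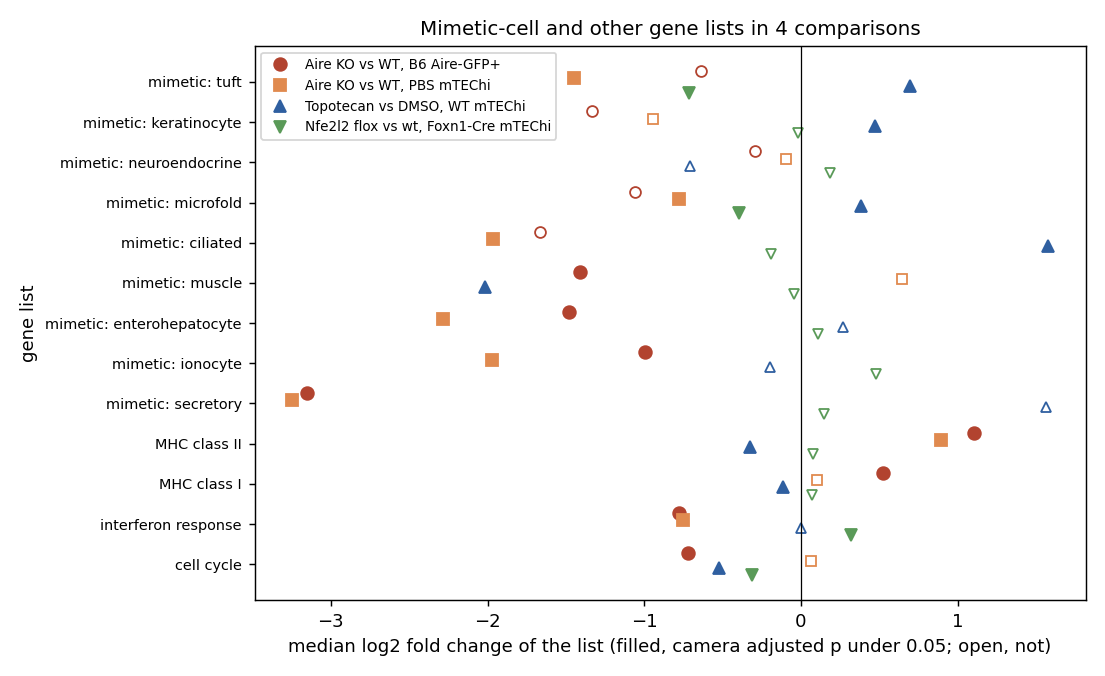
Median log2 fold change (horizontal axis) of 13 gene lists in 4 comparisons, with filled points for camera adjusted p < 0.05 and open points otherwise. MHC class II genes lie at 1.11 in B6 Aire-KO, 0.89 in PBS mTEChi Aire-KO and -0.33 with topotecan.

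Nfe2l2 encodes NRF2, a regulator of antioxidant genes, and the last comparison asks what its deletion in Foxn1-Cre thymic epithelium does to mTEChi. Nfe2l2 did not pass, at 96.0 ± 13.3 CPM in flox against 91.1 ± 0.487 in wt (log2 0.07, SE 0.146, adjusted p = 1, n = 2 each; chromosome 2, 75675513 to 75704641), so gene-level counts do not show a deletion, and which exons are floxed is not given in the sources used here. No gene passed (0 of 18418, edgeR; 973 at unadjusted p < 0.05 with 921 expected; 28 with DESeq2, 0 with limma-voom, 11 without wt replicate 1 and 134 without a low-count filter). Zfp950 (3.25-fold higher, adjusted p = 0.0539) and Grk5 (2.43-fold, 0.135), which overlap on chromosome 19, the collagen Col6a1 (129 to 263 CPM, 0.0894), the chaperone Hspa1a (342 to 186 CPM, 0.231) and Cd4 (52.8 to 18.2 CPM, 0.353) did not pass. The NRF2 target list did not pass: median -0.10 over 36 genes, 0 higher and 0 lower (camera adjusted p = 0.233), with Nqo1 at 45.2 against 59.5 CPM. Aire was 1772 ± 153 against 1877 ± 75.6 CPM (log2 -0.08), and the Aire-induced set had a median of -0.02 (camera direction up, adjusted p = 0.855) and 8.01 ± 0.296% of counts against 8.02 ± 0.0723%.

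By list, in the comparison Nfe2l2 flox vs wt, Foxn1-Cre mTEChi, interferon genes were higher (median 0.32 over 22, 0 passing over all genes, 8 higher and 1 lower over the list alone; camera adjusted p = 1.01e-08, 0.0904 with an estimated correlation), for example Irf7 at 259 against 170 CPM. Tuft genes were lower (median -0.71; adjusted p = 1.01e-08, 0.182 with an estimated correlation), with the tuft cytokine Il25 at 0.591 against 6.43 CPM, and so were heat shock genes (median -0.33; 7.01e-08 and 0.182; 5 lower over the list alone). These 3 calls held in every leave-out. Cell cycle (median -0.31, adjusted p = 6.81e-04), immediate early (-0.31, 8.83e-04), microfold (-0.39, 9.98e-04) and immature mTEC (0.22, 0.00615) lists passed too, without a passing member and at 0.545, 0.4435, 0.371 and 0.371 with an estimated correlation. Cell cycle and immediate early calls are lost without wt replicate 1 (0.520 and 0.0540), immediate early and immature mTEC calls without flox replicate 1 (0.0629 and 0.124), microfold and immature mTEC calls without wt replicate 2 (0.1335 and 0.0780), and the microfold call without flox replicate 2 (0.111). The erythroid list (median -1.38, adjusted p = 0.0658) and the thymocyte list (-0.11) did not pass.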

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

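None of the tests of this part was chosen after its result was seen; they drew attention because the response of a gene list to spermidine differed between WT and Aire-KO mTEChi. Interferon genes differed by a median log2 of -0.25: Isg15 read 54.7 against 60.1 CPM in WT cells and 27.2 against 19.0 CPM in Aire-KO cells, spermidine against PBS. No member passed over all genes, the adjusted p was 0.391 with an estimated correlation, and without WT PBS replicate 2 the median is -0.08 (adjusted p = 0.174).

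The thymocyte list had a median difference of -0.81 (Spermidine effect, WT minus Aire-KO mTEChi) without a passing member, and the adjusted p was 0.391 with an estimated correlation. Cd3e read 12.9 against 2.86 CPM in Aire-KO cells and 4.37 against 2.85 in WT cells. The source of these reads was not tested; thymocytes carry CD45, and CD45+ cells were depleted with magnetic beads before mTECs were sorted by flow cytometry. Without WT PBS replicate 1 the median is -0.29 (adjusted p = 0.189). The erythroid list had a median difference of -3.02, also without a passing member over all genes and with an adjusted p of 0.391 with an estimated correlation. Hemoglobin reads were low in WT spermidine libraries, Hbb-bs 3.60 against 115 CPM, and uneven in Aire-KO cells, 73.8 and 0 CPM in the spermidine libraries against 33.4 and 42.5 with PBS. Without Aire-KO spermidine replicate 1 the erythroid median turns to 1.83 (adjusted p = 0.625), so 1 library carries its direction, and the cause was not tested.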

How the results depend on the processing

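The alternatives below were chosen before the data were examined except 3 added after seeing them: B6 tested per transcript, topotecan with all mTEChi libraries thinned to the smallest total, and the fixed lists under other scaling. The cause of a shift was not tested unless stated.

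Counts of calls moved as follows. In PBS Aire-KO against WT (1896), glmTreat gave 618, limma-voom 1068 (763 higher, 305 lower) and single leave-outs 636 to 1185. In B6 (7410), glmTreat gave 3878, per transcript 4938 and leave-outs 4785 to 6961. In NOD (2018), glmTreat gave 871, limma-voom 1026 (744 higher, 282 lower), DESeq2 3069 and leave-outs 472 to 1498. Topotecan (120) gave 1006 without a filter, 194 with 10 counts in every library of a group, 14 with glmTreat, 60 with limma-voom, 411 with DESeq2, 1 with only its own libraries, 99 after thinning and 45 to 170 over leave-outs. Spermidine in WT (0) gave 111 without a filter and 0 to 1 over leave-outs. Spermidine in Aire-KO cells (1) gave 76 without a filter, 0 with glmTreat, 3 with DESeq2 and 0 to 0 over leave-outs. The difference (0) gave 78 without a filter, 1 with limma-voom, 3 with DESeq2, 1 with its own libraries and 0 to 2 over leave-outs. Nfe2l2 (0) gave 1 with library totals, 134 without a filter, 28 with DESeq2, 1 with its own libraries and 0 to 11 over leave-outs.

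With the replicate number as a replicate block, calls were 93 in NOD, 196 for topotecan and 1 for the spermidine difference. Correlations of library residuals between same-numbered libraries ran from -0.0409 to 0.136, which with 2 or 3 replicates per group leaves open whether the numbers pair libraries.

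Of the medians of the Aire-induced set near 0, all turned direction except spermidine in Aire-KO cells, whose reported median of 0 has no direction to turn. Aire-induced set median log2 fold change, Spermidine effect, WT minus Aire-KO mTEChi, went to -0.0217 with the set of 4-fold genes, -0.00947 with library totals alone and -0.147 to 0.115 over leave-outs. Spermidine in WT ran from -0.0755 to 0.111, and in Aire-KO cells from 0 to 0.0428. Topotecan turned to 0.154 and Nfe2l2 to 0.0546 with the set of PBS mTEChi, with leave-outs of -0.176 to 0.0523 and -0.116 to 0.0630. PBS Aire-KO stayed at -1.64 to -1.16. The set of PBS mTEChi shares PBS libraries with the spermidine comparisons and was not read there.

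Fixed lists called, with an estimated correlation and with fry, were 0 and 14 in B6 (9), 4 and 10 in PBS Aire-KO (10), 0 and 0 for spermidine in WT (3), 1 and 0 in Aire-KO cells (7), 0 and 0 for the difference (3), 0 and 2 for topotecan (9) and 0 and 0 for Nfe2l2 (7); fry also called an unchanged simulated list in B6, PBS Aire-KO and topotecan. Over leave-outs they were 5 to 12, 10 to 12, 4 to 9, 4 to 14, 1 to 8, 8 to 11 and 5 to 7. With library totals alone the B6 class I MHC list went to adjusted p = 0.224 and the PBS Aire-KO ciliated list to 0.0608.

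Aire log2 fold change, Aire KO vs WT, B6 Aire-GFP+, was 0.398 with an offset for effective length, -0.411 with library totals alone and -0.122 to 0.116 over leave-outs, so no direction of Aire holds in B6. It ran from 1.36 to 1.63 in PBS Aire-KO, -1.08 to -0.70 with topotecan (highest adjusted p = 0.0784, and 0.288 with its own libraries) and -0.177 to 0.00711 in Nfe2l2 flox, where Nfe2l2 ran from -0.0688 to 0.208. Of 1234 values of named genes over alternatives, 1000 kept direction and call, 229 lost the call (116 of them with a library left out), 4 turned and 1 gained. The correlation of the topotecan change with gene length was 0.0586 with summed exons, 0.0656 at 10 CPM or more and -0.0311 to 0.0296 over leave-outs.

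Not run, for want of NOD gene names: the set of genes lower in both strains and both strains in one fit.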

Other observations

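Of the tests below, the tests of genes near Aire, of a common factor, the 3 tests of lower Aire, the depth test and the transcript view were chosen only after results were seen. The tests of topotecan against genes changed in PBS mTEChi Aire-KO cells, by camera, overlap and correlation, were not part of the plan either. In B6 Aire-GFP+ cells the level total of Aire hides a change between its transcripts: of 9 tested, 1 rose, 3 fell and 5 did not pass. ENSMUST00000143548.7 rose in Aire-KO cells from 27.6 to 596 CPM (log2 4.43, SE 0.102, adjusted p = 0.00154, edgeR). ENSMUST00000128241.7 fell from 356 to 68.6 CPM (log2 -2.37, adjusted p = 0.0211), ENSMUST00000145975.7 from 169 to 64.3 CPM (-1.40, 0.00698) and ENSMUST00000143735.7 from 32.6 to 11.9 CPM (-1.45, 0.0320). The most abundant, ENSMUST00000131028.7, read 787 against 1065 CPM in WT and did not pass (adjusted p = 0.0608). The kallisto split of reads between overlapping transcripts is an estimate.

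With topotecan, genes called higher in PBS mTEChi Aire-KO cells leaned down, against the direction of Aire loss; the genes called lower there and the sets from B6 cells did not pass. Genes higher in PBS Aire-KO cells (960) had a median log2 of -0.22 with topotecan (camera p = 7.72e-14, 0.00469 with an estimated correlation), and genes lower in Aire-KO cells (936) a median of 0.15 without passing (0.0836 and 0.0606). The Aire-repressed set of B6 cells leaned the same way, with a median of -0.036 (camera p = 0.298, 0.442 with an estimated correlation), and the Aire-induced set went slightly the way of Aire loss (-0.042; 0.269 and 0.145). Of 36 genes higher with topotecan, 15 were lower in Aire-KO cells (1.83 expected, Fisher exact adjusted p = 1.42e-10) and 0 higher. Without DMSO replicate 1 this overlap is 1 of 6 (adjusted p = 0.358) and without DMSO replicate 2 it is 3 of 18 (0.0806). The Spearman correlation of both changes was -0.144 over all genes and -0.213 over 11510 genes at 10 CPM or more, with genes not independent replicates.

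Genes higher in Aire-KO cells of both B6 and PBS mTEChi (628) could come from a strain variant carried with the targeted Aire locus. Only 6 of them (0.955%) lie within 10 Mb of Aire, against 227 of 15649 tested genes (1.45%, odds ratio 0.646, interval 0.234 to 1.44, Fisher exact p = 0.392). These genes were thus not found more often near Aire than other tested genes. With only 227 tested genes in the window, a linked segment could not give all 628 whatever the data. The test therefore cannot decide on the group as a whole. A variant acting on distant genes was not tested. The limit first set for this share was dropped after its value was seen, because the number of genes near Aire nearly fixed its outcome. Among the 6, Dnmt3l overlaps Aire on chromosome 10 (78041947 to 78063622). It rose by log2 1.62 in B6 and 2.58 in PBS mTEChi (edgeR adjusted p = 6.61e-05 in mTEChi), and the reason was not tested. Of the 612 genes lower in both, 14 lie within 10 Mb of Aire. A common factor, from the TMM scaling or from the counts that the Aire-induced set gives up, would raise all other genes alike. It was tested on genes called higher in one library set and measured in the other, after earlier versions of the test had been replaced with their values known. The 3228 genes called higher in B6 had a median log2 of 0.322 in PBS mTEChi, 0.4964 above the other genes and above matched random lists (0.0489 to 0.0851; camera p = 5.73e-26, 8.99e-07 with an estimated correlation). The 880 called higher in PBS mTEChi had one of 0.8115 in B6, 0.976 above the other genes and above random lists (0.255 to 0.362; camera p = 3.71e-48, 0.00981 with an estimated correlation). With each library left out the distances ran from 0.481 to 0.545 and from 0.956 to 1.04; the choice of scaling cannot move them, so it is no test here. The random lists and camera also measure these genes against other tested genes, which a common factor would move as well. They show that the genes rank above others in both library sets, but cannot decide on a common factor. The size of the rise does depend on scaling: with library totals alone the medians were 0.136 (quartiles -0.141 to 0.492; 2014 of 3228 positive) and 0.411 (-0.0317 to 0.895; 649 of 880 positive). Of the 628 genes, 608 stay positive in both with library totals and 304 (48.4%) stay called. In the 324 others the median log2 goes from 0.786 (quartiles 0.567 to 1.07) to 0.387 (0.167 to 0.673) in B6 and from 0.808 (0.636 to 1.09) to 0.622 (0.450 to 0.900) in PBS mTEChi, while the median SE goes from 0.140 to 0.138 and from 0.187 to 0.186, so the folds shrink and the SE hardly moves.

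Genes lower with topotecan could follow its lower Aire, a call that is itself lost without DMSO replicate 1 (adjusted p = 0.0784) and with the 4 libraries fitted alone (Aire log2 fold change, Topotecan vs DMSO, WT mTEChi, adjusted p = 0.288). For 32 of the 84 only their direction speaks against this, as they are higher in PBS Aire-KO cells. They were picked by that direction, so the overlap test bears on their number alone (4.38 expected, Fisher exact adjusted p = 2.47e-19). It counts genes as independent, and genes lower in both also exceed their expected number. Whether lower Aire or another action lowers the 20 that are lower in both (4.27 expected, adjusted p = 7.00e-09; 23.8% of 84, exact interval 15.2 to 34.4%) cannot be told apart, since the set as a whole did not fall (camera p = 0.269); 13 of 39 without DMSO replicate 1 are lower in both and 7 higher in Aire-KO cells. Another idea is library depth: the topotecan and DMSO libraries differ in total counts. With both groups thinned to 2890040 counts, a median of 94.6% of the 84 were still called lower (84.5 to 97.6% over 10 thinnings). These calls thus do not need unequal totals. The test was mild, since mean totals were close (3348555 in DMSO, 2921486 with topotecan) and thinning removed few counts. With all mTEChi libraries thinned to 2027205 counts, 57 of the 84 were still called lower. An earlier test on kept folds was dropped, since thinning leaves the expected fold as it was. The single share of 23.8% was dropped once after its first value was seen and was then restored, and the 2 tests on the 32 and the 20 were split after both counts were known.

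Cep85, Ubxn11 and Sh3bgrl3 lie side by side on chromosome 4 and read lower with spermidine in Aire-KO mTEChi, which a genomic segment that differs between mice could give. Of 89 other tested genes within 2 Mb, 6 (6.74%, exact interval 2.51 to 14.1%; 5 lower) had an unadjusted p < 0.05, against 4.09% of all other genes (Fisher exact p = 0.183). The value is under the limit of 10% written before, but a demand that the interval stay under it was added after the value was seen, so a segment and an effect on Cep85 cannot be told apart. Cep85 was high only in the Aire-KO PBS libraries (1257 and 1104 CPM). For NOD, 10 splits of the 6 libraries are too few for a share under 0.05; 1 split, the real one, reached 2018 calls, and the highest other gave 2.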
